A study of Mus musculus with 4 samples.

How the data were processed

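Small RNA was sequenced from mouse embryonic fibroblasts (MEFs, primary cells grown out of mouse embryos) that carry a short hairpin RNA (shRNA) against luciferase, a gene mice lack. The 4 libraries form 4 groups of 1 library, per the labels' titles: cells without a transactivator and cells that also carry ROSA-rtTA, each without and with doxycycline (dox). rtTA, the reverse tetracycline transactivator, switches on a tetracycline-responsive promoter when dox is present, and ROSA names the Rosa26 locus, which is active in most mouse tissues. Per the labels, RNA was taken out by phenol and chloroform extraction.

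The values deposited by the authors are raw counts of reads, 1 count per microRNA and library, with 1 further count for a row that names the luciferase shRNA; the file headers give the library title and name no processing step. The values are whole numbers from 1 upward, and a microRNA that a library does not list was taken as 0. The aligner, the number of mismatches allowed, the treatment of reads that fit several microRNAs, the microRNA database version and the genome build are not given in the sources used here. Reads shared by near-identical microRNAs could thus have been split or counted more than once: of the 372 microRNAs that entered the comparisons, 92 have another listed microRNA at most 2 mismatches away. Star names (miR-30b*) mark the arm of a hairpin that was listed as the passenger strand. Results with passenger strands left out drop star names only. Some star arms were the more abundant of their pair (miR-136*, miR-140*, miR-193* and miR-455*) and were dropped too. Rarer arms named -3p or -5p, such as miR-337-3p, were kept.

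The libraries hold 6383594 counts (no rtTA, -dox), 6545093 (no rtTA, +dox), 8780954 (rtTA, -dox) and 7690978 (rtTA, +dox). CPM, the count of a microRNA per 1000000 endogenous microRNA counts of its library, were computed for each microRNA. This scaling left out the shRNA, which held between 0.0725% and 2.38% of all counts. A microRNA was compared if its mean CPM over the 4 libraries equalled at least 20 counts in the shallowest library, which is 3.14 CPM. Of 508 microRNAs, 372 passed, with 99.99% of the endogenous counts and none at 0 in any library. A count of 0 would allow up to 0.470, 0.459, 0.342 and 0.400 CPM in the 4 libraries in the order above (3 counts).

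For each comparison of 2 libraries the log2 ratio of CPM was taken with an exact conditional binomial (Clopper-Pearson) 95% interval, and a microRNA was counted as higher or lower if it was at least 2-fold apart with an interval that excluded equality. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals of ratios and shares and the floors cover counting error only. Intervals of list medians, of the slope on the percentage of C, of correlations between arms and of the other-arm median come from resampling microRNAs or hairpins. These are not independent replicates, and such intervals do not cover the spread between libraries. With 1 library per group no difference has a replicate check, and the values compare libraries, not conditions. No p-value was computed for these comparisons. The difference of the dox ratios with and without rtTA was given a delta-method interval with 0.5 added to each count. Correlations between libraries used log2(CPM + 1).

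The 20 microRNA lists (families, clusters, response markers, and markers of fibroblasts and other cell types) were compared by the median log2 ratio of their members past the floor; all log2 ratios and CPM are own computations from the deposited counts. The median was placed among 10000 random lists of the same size, drawn with replacement from neighbours in mean abundance. This percentile describes these libraries and is not a test. Random members were drawn independently, while the lists hold both arms of some hairpins and members of shared clusters. Where such members move together, the percentiles look more extreme than they are. Lists outside the central 95% of the random lists are named as standing apart, and lists with fewer than 3 members have no percentile. Standing apart does not mean that the members shifted together. The 95% resampling interval of the median spanned 0 for let-7 (dox in rtTA cells), miR-15/16 (dox without rtTA), and miR-30 and mesenchymal (rtTA without dox). It excluded 0 for the other lists that stood apart with the main processing. The share of the rarer arm was computed for 125 hairpins with at least 20 counts over both arms in each library. Arms were paired by name, so a microRNA that matches several precursors can hold counts of more than 1 hairpin.

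A secondary fit over all 4 libraries used edgeR's quasi-likelihood test with TMM factors and additive terms for dox and rtTA, which leaves 1 residual degree of freedom and assumes that dox acts alike with and without rtTA; p-values were adjusted by the Benjamini-Hochberg method. The named microRNAs are the shRNA, the 10 most abundant, up to 8 per direction and comparison with the largest ratios among those counted as higher or lower, and up to 4 of the most abundant members of each list. Any others named fall outside this rule and were picked after the data were seen, such as let-7c-1*, let-7f*, miR-382* and miR-1193. Groups, tests, lists, the naming rule and the alternatives called planned were fixed before the data were examined. Alternatives were other scalings, floors, fold limits, summed or left-out rows, DESeq2, and, added after seeing the data, left-out near-identical microRNAs, cluster members taken by location, corrections for base composition and a fit of 1 library against the other 3. Of the composition corrections 5 were tried, and the correction on the percentage of G was chosen from them after all 5 had been seen.

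Mature sequences were matched exactly to the annotated microRNA precursors of GENCODE M21 (GRCm38): 497 of the 508 matched, 62 of them to more than 1 precursor. Coordinates are 1-based in that build and come from this match, not from the deposited counts.

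The steps were tested on simulated data. For the comparison of dox in rtTA cells, with Poisson counts for 508 microRNAs of which 200 were changed, 387 passed the floor. All 80 changed by 3-fold and all 77 changed by 4-fold were recovered, with 0 of 230 unchanged ones counted and 95.3% of the intervals holding the true value. Poisson counts hold counting error only, so these values check the computation and give no rate of false calls between real libraries. A slope made as 0.4 log2 per 10 percentage points of G came back as 0.407. The additive fit below was given only changes alike at both levels of the other factor. A change in the induced library alone was not simulated for it. With negative binomial counts for 372 microRNAs, the dox term of the additive fit recovered 91 of 100 at 3-fold and 97 of 100 at 4-fold, the rtTA term 74 and 94 of 100, and the fit of 1 library against 3 recovered 90 and 98 of 100. Of 172 unchanged microRNAs these called 0, 0 and 5.

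Tools were Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 (loaded by edgeR) and DESeq2 1.42.0.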

Results

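Endogenous microRNAs and a luciferase shRNA were counted in 4 small RNA libraries of mouse embryonic fibroblasts, 1 library per group (rtTA absent or present, each without and with dox), with 6383594 to 8780954 counts each. The libraries listed between 462 and 477 endogenous microRNAs. In each library the 10 most abundant took 60.9% to 61.4% of the endogenous counts. miR-21, abundant in fibroblasts and other mesenchymal cells, alone took 23.0% (no rtTA, -dox), 21.3% (no rtTA, +dox), 20.7% (rtTA, -dox) and 19.4% (rtTA, +dox). It was followed by miR-22 and miR-143, then miR-29b, miR-29a, miR-24, let-7i, let-7c, miR-31 and miR-130a. miR-21 lies on chromosome 11 at 86584120 to 86584141 on the minus strand, in an exon of Vmp1. Across the 372 microRNAs past the floor, the Pearson correlation of log2 CPM ran from 0.980 (rtTA +dox against no rtTA +dox) to 0.995 (the -dox libraries).

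The shRNA level set the induced library far apart from the others. It held 4630 counts in the library without rtTA and without dox, 0.0725% of all counts (95% interval 0.0705% to 0.0746%, Clopper-Pearson). The other uninduced libraries held 5063 counts (0.0774%, 0.0752% to 0.0795%; no rtTA, +dox) and 6898 counts (0.0786%, 0.0767% to 0.0804%; rtTA, -dox). In rtTA cells with dox it held 183085 counts, 2.38% (2.37% to 2.39%). Among the listed RNAs it ranked 8 in that library and 108, 102 and 101 in the others. In CPM of endogenous counts the induced library was 31.0-fold (30.3 to 31.8) above rtTA cells without dox and 31.5-fold (30.6 to 32.4) above dox-treated cells without rtTA. Dox without rtTA gave 1.07-fold (1.02 to 1.11), and rtTA without dox gave 1.08-fold (1.04 to 1.12). The row for the shRNA is 324 bases long and holds a perfect stem of 23 base pairs, CCGCCTGAAGTCTCTGATTAATA at bases 130 to 152 and TATTAATCAGAGACTTCAGGCGG at bases 168 to 190, around a loop of 15 bases.

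**Figure D1:**
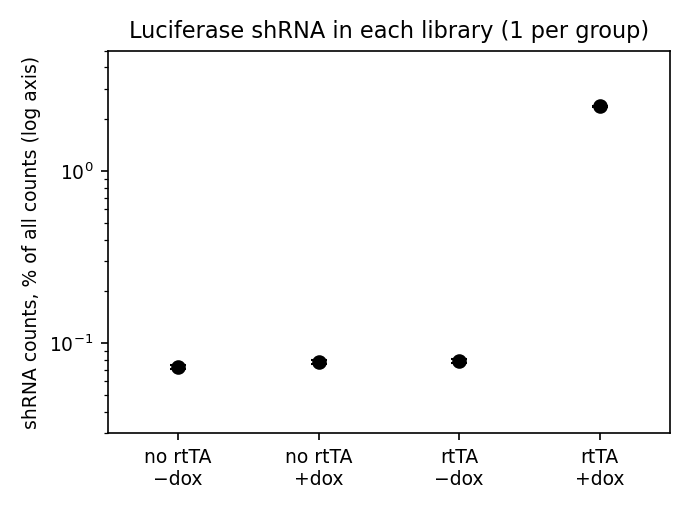
Share of all counts on the luciferase shRNA row, in percent on a log axis, for each of the 4 libraries (1 point per library; bars, 95% Clopper-Pearson interval, counting error only). The induced library lies at 2.38% and the others between 0.0725% and 0.0786%.

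Dox in rtTA cells addresses whether a strongly expressed shRNA, which is processed like a microRNA, goes with a changed pool of endogenous microRNAs. Most microRNAs differed little: 260 of 372 (69.9%) lay within 1.5-fold between the induced and the uninduced rtTA library. Counted by the 2-fold rule, 5 were higher and 32 lower with dox. The higher ones were miR-323-5p (log2 ratio 1.48, 95% interval 1.13 to 1.85) and miR-370 (1.10, 1.01 to 1.19) of the imprinted Dlk1-Dio3 cluster, miR-351 (1.26, 1.21 to 1.31; chromosome X, 53053315 to 53053338, minus strand), miR-30b* (1.14, 0.80 to 1.49) and miR-672 (1.13, 1.07 to 1.19). The lowest ratios were those of miR-466e-3p (-2.17, -2.47 to -1.87), miR-669f (-2.07, -2.25 to -1.90), miR-297c* (-1.89, -3.12 to -0.82, on 39 and 9 counts) and miR-466d-3p (-1.82, -2.30 to -1.37). These match hairpins within Sfmbt2 on chromosome 2, which holds a large rodent cluster of related microRNAs (miR-669f at 10467285 to 10467307, plus strand). They were followed by miR-15b (-1.56, -1.61 to -1.51; chromosome 3, 69009775 to 69009796, within Smc4), miR-674* (-1.51), miR-495 (-1.51) and let-7c-2* (-1.50). Of these, miR-466e-3p, miR-466d-3p and miR-669f have near-identical listed microRNAs, so their counts are uncertain between copies.

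The let-7 family, known for holding back proliferation, had a lower median in the induced library, but none of its guide strands was counted as lower. The median of its 16 members was -0.40 (resampling interval -0.54 to 0.0079), at percentile 1.4 of the random lists. Of the 16, 12 lay below 0, 0 were counted as higher and 3 as lower. These 3 were passenger strands of low G content (let-7c-1*, let-7c-2* and let-7f*, 4.55% to 9.09% G). With passenger strands left out the median of the other 9 members was -0.35 (percentile 2.46), with 0 counted, and without near-identical microRNAs the median of the 5 members left was -0.60, with 2 counted as lower, at percentile 15.9. With a linear trend on GC content subtracted, an alternative added after seeing the data, the median was 0.048. Among its abundant members let-7f was at -0.49 and let-7a at -0.35, while let-7i was at 0.15 and let-7c at 0.38. No other list stood apart, but without near-identical microRNAs the miR-34 family did (median -0.92 over 3 members, percentile 0.43), against 0.11 over all 5. The Dlk1-Dio3 list had 2 of 64 members higher and 5 lower (median -0.05), and the Sfmbt2 list 0 of 20 higher and 3 lower (-0.16). These lists were fixed by name and are incomplete: the Sfmbt2 list lacks miR-466e-3p and miR-669f and holds miR-466i, which matches a hairpin on chromosome 13, and the Dlk1-Dio3 list lacks miR-1193. Taken by location, an alternative added after seeing the data, 0 of 24 microRNAs within Sfmbt2 were higher and 4 lower (median -0.20), and 2 of 67 in the chromosome 12 cluster were higher and 6 lower (-0.06). Of the miR-15/16 family 2 of 8 members were lower (-0.31), and of the miR-23/27/24 clusters 2 of 9 (-0.26), with miR-23a at -1.04. The miR-30 family, which lends its backbone to many shRNA vectors, had a median of -0.02 over 10 members, a value that is slightly above 0 under TMM and DESeq2 scaling, with miR-30a at -0.22 and miR-30e at 0.03. Medians were 0.10 for the miR-17~92 clusters (17 members), -0.36 for the miR-29 family (6), 0.11 for the p53-responsive miR-34 family (5), -0.20 for miR-221 and miR-222 (2 members), -0.11 for the inflammatory list (3) and -0.03 for the mesenchymal list (20; above 0 by TMM and DESeq2 scaling). The hypoxia marker miR-210 had a ratio of 0.82. Markers of other cell types had medians of -0.50 (blood, 4), -0.44 (muscle, 3), -0.01 (neuronal, 7; above 0 under TMM, DESeq2 and scaling without the 10 most abundant) and -0.52 (endothelial, 2), and the liver marker miR-122 was at -0.10. After the trend on G was subtracted, values nearer 0 included those of the miR-17~92 clusters (0.0034), miR-29 (0.03), Dlk1-Dio3 (0.03), blood (0.02), muscle (-0.05), endothelial (-0.33) and miR-210 (0.26). Farther from 0 were miR-34 (-0.13), miR-30 (0.14), the mesenchymal (0.11) and neuronal (0.20) lists, and miR-122 (-0.66). No member of the epithelial and pluripotent lists passed the floor.

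The ratios in this comparison moved with the base composition of the mature sequences: across microRNAs, which are not independent replicates, the Pearson correlation with the percentage of G was 0.72 and with the percentage of C -0.24. Median ratios in 5 classes of rising G content were -0.57, -0.17, -0.10, 0.17 and 0.44. The microRNAs counted as lower had a median of 9.09% G and those counted as higher 43.5%, against 23.8% over all 372. After a linear trend on G was subtracted, an alternative added after seeing the data, 3 were higher and 5 lower, 6 of them among the 37 counted before (miR-1, miR-15b, miR-351, miR-466d-3p, miR-466e-3p and miR-669f). The let-7 median then was -0.26, at percentile 2.76. With 1 library per group, none of the differences here or in the other comparisons has a replicate check; they compare libraries, not conditions.

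**Figure D2:**
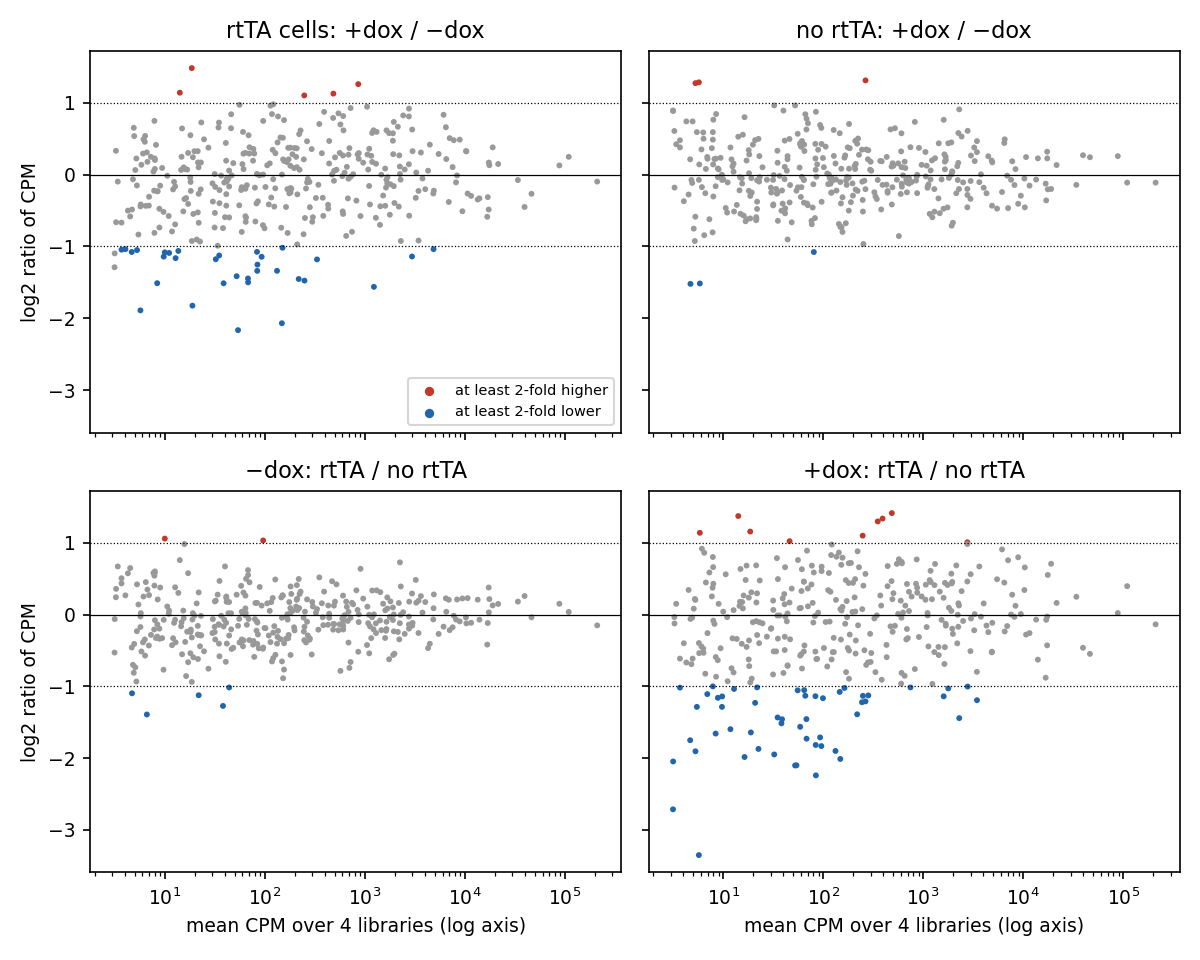
Log2 ratio of CPM against mean CPM (log axis) for 372 microRNAs in the 4 comparisons, 1 point per microRNA; dotted lines mark 2-fold. With dox in rtTA cells 5 were higher and 32 lower, without rtTA 3 and 3; rtTA against none gave 2 and 5 without dox and 9 and 53 with dox.

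**Figure D3:**
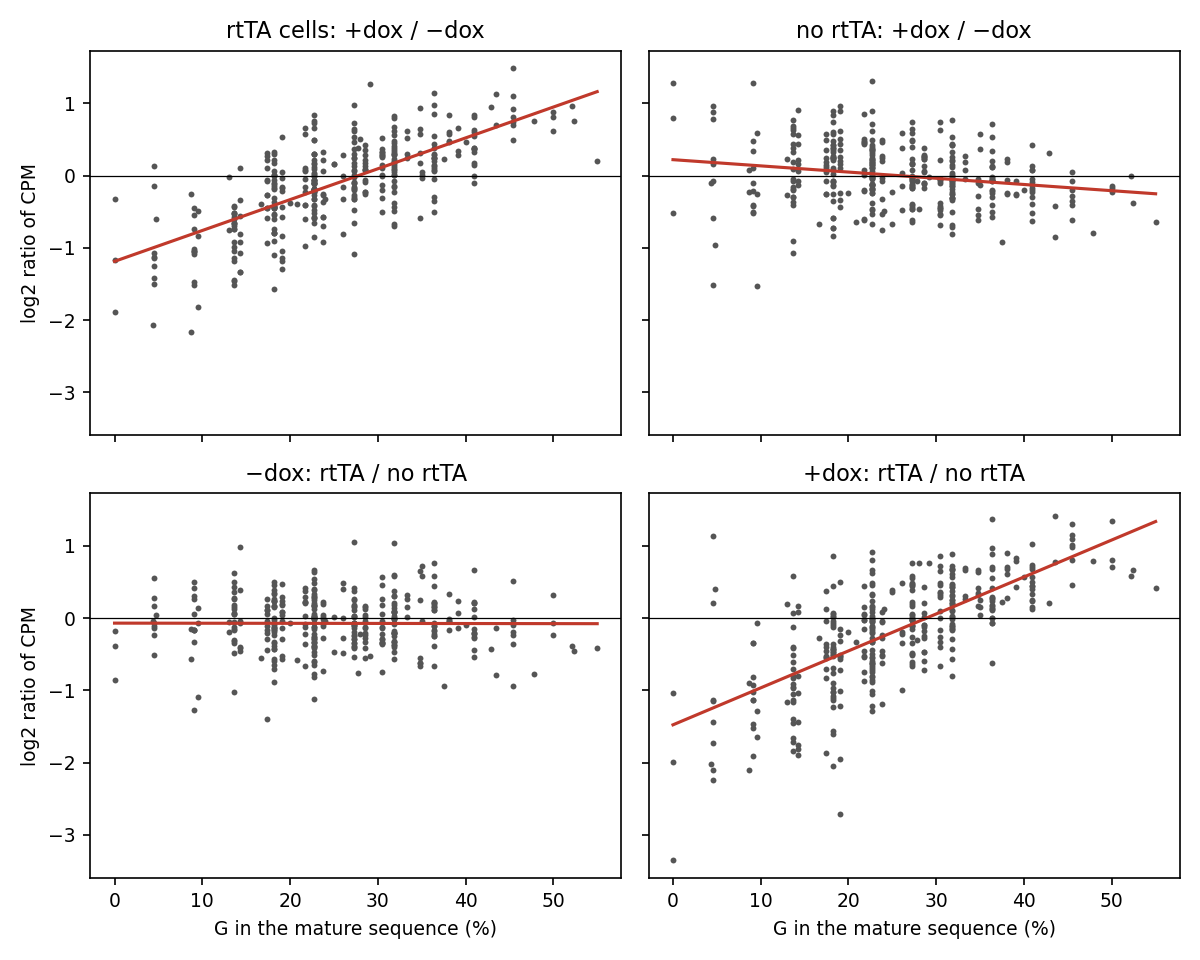
Log2 ratio of CPM against the percentage of G in the mature sequence for the same 372 microRNAs and 4 comparisons; red lines are least-squares fits. The slopes per 10 percentage points of G are 0.43 and 0.51 log2 in the comparisons that hold the induced library (rtTA cells with dox), and -0.09 and -0.0014 in the others.

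Dox without rtTA separates the drug from the shRNA, since the shRNA stays uninduced. Fewer microRNAs were apart: 309 of 372 (83.1%) lay within 1.5-fold, 3 were higher and 3 lower. Higher with dox were miR-29a* (1.31, 1.22 to 1.41), miR-297c* (1.29, 0.68 to 1.93) and miR-130b* (1.27, 0.58 to 2.01), and lower were miR-702 (-1.52, -2.34 to -0.76), let-7b* (-1.52, -2.35 to -0.74) and miR-532-3p (-1.08, -1.28 to -0.88). Apart from miR-29a* (1185 and 3018 counts) and miR-532-3p (624 and 303), these rest on 19 to 80 counts per library. In the no rtTA, -dox library miR-702 was at least 2-fold above each other library, and that library also enters rtTA without dox. In the no rtTA, +dox library miR-29a* and miR-297c* lay at least 2-fold above and let-7b* below each other library. That library also enters rtTA with dox, where let-7b* was counted as higher. miR-29a* lies on chromosome 6 at 31062711 to 31062732 (minus strand) and miR-702 within Plod3 on chromosome 5 at 136991520 to 136991540. With passenger strands left out, 0 were higher and 2 lower. The miR-29 family, which targets collagen and other matrix transcripts, had a median of 0.26 over 6 members (percentile 98.1), with miR-29a at 0.27, miR-29b at 0.24 and miR-29c at 0.38. The miR-15/16 family, known to restrain the cell cycle, had a median of -0.31 over 8 members (percentile 2.13). The resampling interval was -0.53 to 0.16, with miR-15b at -0.59 and miR-322 at -0.47. After the trend on G was subtracted, the miR-29 median was at percentile 93.5 and the miR-15/16 median at 2.38. With near-identical microRNAs left out the medians were 0.18 (miR-29, 4 members, percentile 86.6) and -0.27 (miR-15/16, 6 members, percentile 5.74). Markers of other cell types had medians of 0.37 (neuronal, 7 members, 6 above 0, percentile 94.6), 0.23 (blood, 4), 0.68 (endothelial, 2) and -0.07 (muscle, 3), and miR-122 was at 0.42. With passenger strands left out the neuronal list (0.40 over 6 members, percentile 98.4) and the Sfmbt2 list (-0.27 over 18 members, percentile 2.46) newly stood apart.

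Set against each other, the dox ratios with and without rtTA pointed opposite ways for 213 of 372 microRNAs (57.3%), and their Pearson correlation across microRNAs was -0.19 (Spearman -0.18); the comparisons share no library. For 67 microRNAs the 2 ratios differed by at least 2-fold with a counting interval that excluded equality, 21 higher and 46 lower with rtTA. miR-297c* had the ratios -1.89 with rtTA and 1.29 without, miR-365 -1.41 and 0.96, and miR-323-5p 1.48 and -0.61. With the G trend subtracted from both sets of ratios, 36 differed and the correlation was -0.06.

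rtTA without dox compares the uninduced libraries of both genotypes. They were the closest pair, with 334 of 372 microRNAs (89.8%) within 1.5-fold, 2 higher and 5 lower with rtTA. Higher were miR-1 (1.06, 0.59 to 1.55, on 51 and 146 counts), a microRNA of heart and skeletal muscle, and miR-106b* (1.03, 0.86 to 1.20). In the rtTA, -dox library miR-1 was at least 2-fold above each other library. That library also enters dox in rtTA cells, where miR-1 was counted as lower (-1.08). Lower were miR-667 (-1.39, -2.05 to -0.76), miR-574-3p (-1.27, -1.51 to -1.04), miR-139-5p (-1.12, -1.45 to -0.81), miR-702 (-1.10, -1.74 to -0.47) and let-7d* (-1.02, -1.22 to -0.81). Under TMM, DESeq2 and scaling without the 10 most abundant microRNAs, the split was 3 higher and 4 lower, and with a floor of 5 counts 7 and 7. Of the Dlk1-Dio3 list, a cluster transcribed from the maternal chromosome 12, 1 of 64 members was counted as lower and 0 as higher; the median was -0.22 (percentile 0.02) and 55 members lay below 0. Its abundant members differed, with miR-411 at -0.41, miR-541 at -0.22, miR-379 at -0.02 and miR-376a at 0.04. The mesenchymal list had a median of -0.14 (20 members, percentile 2.02, resampling interval -0.27 to 0.16), with miR-21 at -0.15 and miR-143 at 0.15. The miR-30 family had a median of 0.22 (10 members, percentile 99.3, resampling interval -0.12 to 0.43), which was -0.0048 with passenger strands left out.

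Markers of other cell types also had higher medians in the rtTA library without dox. The muscle list had a median of 0.52 (3 members, percentile 99.1), with miR-206 at 0.52 on 1571 and 3092 counts and miR-133a at 0.45. The neuronal list had a median of 0.29 (7 members, percentile 98.0), with miR-9 at 0.29 and miR-129-5p at 0.32, and all 7 members were above 0. The blood list had a median of 0.40 (4 members, percentile 96.3), with miR-142-5p at 0.98. Without near-identical microRNAs the Dlk1-Dio3 list (median -0.22, percentile 0.06) and, newly, the miR-17~92 clusters (0.35 over 9 members, percentile 99.8; 0.11 over all 17) stood apart. The neuronal median stayed at 0.29 (percentile 97.0) and the mesenchymal median was -0.12 (29.6), both about as large as before, while the miR-30 median was 0.09 (74.0) and the muscle median 0.79 over 2 members, too few for a percentile. With passenger strands left out the mesenchymal list no longer stood apart (-0.12, percentile 4.38), while the miR-34 family (-0.40, percentile 2.35) and the blood list (0.40, percentile 98.7) newly did. The ratios of this comparison had a correlation of -0.0038 with the percentage of G.

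rtTA with dox compares the induced library with dox-treated cells that lack the transactivator, and shares the induced library with the first comparison. It showed the most differences: 226 of 372 microRNAs (60.8%) lay within 1.5-fold, 9 were higher and 53 lower in the induced library. The 8 highest were miR-672 (1.41, 1.34 to 1.49), miR-30b* (1.37, 0.97 to 1.79), miR-483 (1.34, 1.26 to 1.42) from within Igf2, miR-206 (1.30, 1.21 to 1.38; chromosome 1, 20679055 to 20679076), miR-323-5p (1.16), let-7b* (1.14), miR-370 (1.10) and miR-675-5p (1.02) from an exon of H19. The 8 lowest were miR-297c* (-3.35, -4.53 to -2.35, on 80 and 9 counts), miR-1197 (-2.71, -4.12 to -1.54, on 40 and 7), miR-350 (-2.24, -2.45 to -2.04), miR-365 (-2.10), miR-466e-3p (-2.10), miR-19a* (-2.05), miR-669f (-2.01) and miR-467d* (-1.98).

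Of the Dlk1-Dio3 list, 13 of 64 members were lower and 2 higher in the induced library, with a median of -0.38 (percentile 0.30); by location 15 of 67 were lower and 2 higher (-0.42). With star names left out its median was -0.21 over 52 members (percentile 2.6), with 10 lower and 2 higher. This dropped miR-136*, the more abundant arm of its pair, and kept rarer arms such as miR-337-3p. Without near-identical microRNAs the miR-34 family newly stood apart (-0.95 over 3 members, percentile 2.38; -0.33 over all 5), and the muscle list kept 2 members. The muscle list had a median of 0.86 over 3 members (percentile 98.7), 1 of them higher. The 9 counted as higher had a median of 45.5% G and the 53 counted as lower 13.6%. The correlation of the ratios with the percentage of G was 0.69, and after the trend was subtracted 8 microRNAs were higher and 13 lower, 13 of them among the 62 counted before. The Dlk1-Dio3 median then was -0.13 (percentile 1.92) and the muscle median 0.45 (percentile 92.7). TMM and DESeq2 factors raised every log2 ratio of this comparison by 0.101 and 0.104, which gave 13 higher and 42 lower with either.

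**Figure D4:**
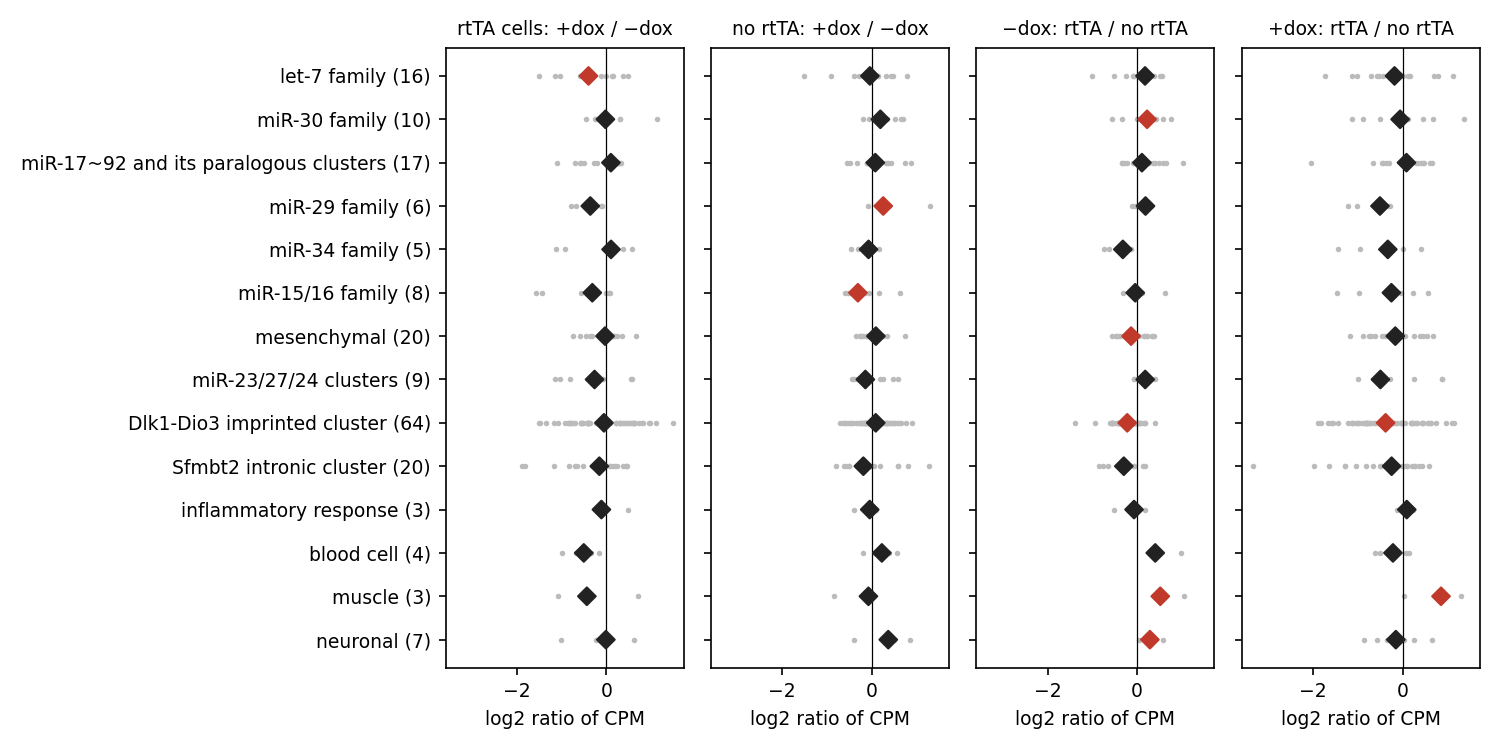
Log2 ratios of the members (grey points) and their median (diamonds) for the 14 microRNA lists with at least 3 members past the floor, in the 4 comparisons; the number of members stands in parentheses. Red diamonds lie outside the central 95% of 10000 abundance-matched random lists, such as let-7 with dox in rtTA cells (median -0.40) and the Dlk1-Dio3 cluster in both comparisons of rtTA against none (-0.22 and -0.38).

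The arms of 125 hairpins were compared by their shares. The rarer arm held a median of 4.68% of the counts of both arms (no rtTA, -dox), 5.30% (no rtTA, +dox), 5.13% (rtTA, -dox) and 4.44% (rtTA, +dox). With dox in rtTA cells the odds of the rarer arm were at least 2-fold higher in 5 hairpins and lower in 20, with a median log2 odds ratio of -0.08. With dox alone these were 4 and 3 hairpins (median 0.05), with rtTA alone 3 and 2 (-0.04), and with rtTA under dox 8 and 23 (-0.07). The odds moved with the difference in G content between the arms in both comparisons that hold the induced library, with Pearson correlations across hairpins of 0.66 and 0.66, against -0.01 (dox alone) and 0.11 (rtTA alone). In the 20 hairpins with lower odds, such as those of miR-382* and miR-674*, the rarer arm had a median of 9.09% G and the other arm 32.6%.

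The additive edgeR fit over all 4 libraries called 0 of 372 microRNAs for dox at an adjusted p of 0.05, with 11 at an unadjusted p below 0.05, and DESeq2 called 0 and 11. For rtTA edgeR called 0, with 25 at an unadjusted p below 0.05, and DESeq2 0 and 15. The fit assumes that each factor acts alike at both levels of the other. A change in the induced library alone would enter its spread in part, so these counts do not argue against one. Without the floor, edgeR called miR-205, an epithelial marker, higher with rtTA (log2 fold 2.66, adjusted p = 0.00582). Its counts were 4 and 6 without rtTA and 76 and 17 with rtTA (-dox and +dox), and it was named after its values were seen.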

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

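All tests in this part were chosen after the results they bear on had been seen. For 14 named microRNAs the ratio of dox to no dox pointed one way in rtTA cells and the opposite way in cells without rtTA, both beyond counting error; the condition that the ratios differ by at least 2-fold was also set after they were seen. With 1 library per group the difference was not tested. The ratio with rtTA was lower for miR-297c* (difference -3.18 log2), miR-365 (-2.38), miR-130b* (-2.33), let-7c-2* (-2.28), miR-126-5p (-2.14), miR-350 (-2.13), miR-29a* (-1.42) and miR-29c (-1.18). It was higher for miR-323-5p (2.09), miR-672 (1.54), miR-370 (1.46), miR-675-5p (1.23), miR-34c (1.03) and miR-483 (1.02).

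Across all 372 microRNAs the dox ratios with and without rtTA had a correlation of -0.19. A candidate explanation is that the ratios follow G content in opposite directions, with slopes of 0.43 and -0.09 log2 per 10 percentage points. After both trends were subtracted the correlation was -0.064. Both trends were fitted to these same ratios, so this change follows from the correlations with G and does not decide on a cause. Opposite responses of the cells to dox stay open as an untested explanation for single microRNAs.

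For the 37 microRNAs at least 2-fold apart between the induced and uninduced rtTA libraries, a candidate explanation is G content: with its trend subtracted 8 were apart, 6 of them among the 37, and the same step left 8 apart for dox without rtTA, 7 for rtTA without dox and 21 for rtTA with dox, so that what remains cannot be told apart from differences between libraries: 1 of the comparisons that hold the induced library is at their level and the other above it. Those no longer counted fell below 2-fold, as did miR-323-5p (1.48, 1.13 to 1.85, before and 0.73, 0.38 to 1.09, after) and miR-370 (1.10, 1.01 to 1.19, before and 0.35, 0.26 to 0.44, after). The trend was fitted to these same ratios, so the smaller count restates their correlation with G. It does not decide whether G content or induction lies behind the differences. A bias of double-stranded amplification would treat C like G. The C slope was 0.123 (0.077 to 0.163) against 0.501 for G. This argues against such a bias as the only cause, while a part stays open. The totals behind these ratios leave out the shRNA, so counts taken up by it do not enter them. With the shRNA in the totals every log2 ratio would shift by 0.034, too little by itself to make a 2-fold difference. Changed transcription would move both arms of a hairpin alike. The other arm, signed by the direction of the first, had a median of -0.41 (-0.58 to -0.065). Of 18 other arms 4 lay on the same side (let-7f, miR-15b, miR-15b* and miR-466d-5p). These ratios hold the G trend, and paired arms can differ in G content, so they do not decide on transcription. The hairpin of miR-15b entered with both arms, and let-7f matches more than 1 precursor. For miR-15b, whose other arm miR-15b* was lower too (-1.56 and -1.45), lower transcription stays open. Induction itself cannot be told apart from a property of this library, because only 1 induced library exists among those used: it had 19 microRNAs at least 2-fold from each of the other libraries, which had 1, 3 and 1.

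The shRNA was also counted in the uninduced libraries, at 0.0725% to 0.0786% of all counts. Misassigned reads of listed microRNAs that match the shRNA row in full and without mismatches are argued against. The longest run of bases that any shares with the row is 12 (miR-505), below the shortest microRNA (16). Matches with mismatches were not examined, and the number of mismatches allowed is not known, so misassignment of that kind stays open. Transcription without the transactivator may contribute. Without dox the level with rtTA was 1.08-fold that without, but carry-over or misassigned reads could also give alike levels, so this value does not decide. In CPM, the shRNA level in rtTA cells without dox was 0.0322 of that in the induced library. Carry-over as the only source there would have to supply that level. The microRNA that limits carry-over most, miR-30b* in the library without rtTA and dox, allows up to 0.371 of the induced level. Transcription without the transactivator and carry-over cannot be told apart, because no microRNA was scarce enough in the uninduced libraries to bound carry-over.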

How the results depend on the processing

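All alternatives on base composition, near-identical microRNAs, clusters by location and 1 library against 3 were added after seeing the data; the others were planned. Leaving out a library was not possible with 1 per group. No paired analysis was possible because the labels carry no replicate numbers; the additive fit compares dox within each genotype through its rtTA term. Of the summary values 105 stayed within 1.5 times or their interval and 43 did not; of 724 list medians 67 changed sign, 18 of them with the G trend and 16 with the GC trend subtracted, including 2 of lists that stood apart; of named ratios 1169 stayed within their counting interval and 611 did not. Other scalings moved no count of microRNAs by over 1.5 times. Where no reason is given, the cause was not tested. Depth limits the low floors, where few counts carry a ratio.

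Counts of microRNAs apart are given as dox in rtTA cells (37), dox without rtTA (6), rtTA without dox (7) and rtTA with dox (62). A fold limit of 1.5 gave 107, 57, 35 and 141, and a limit of 3 gave 4, 0, 0 and 20, by construction. For dox without rtTA and rtTA without dox, a floor of 5 counts gave 10 and 14, a floor of 100 counts 2 and 4, and no floor 11 and 15; without passenger strands dox without rtTA gave 2, with fewer microRNAs compared. With the G trend subtracted, dox in rtTA cells gave 8 and rtTA with dox 21. With the GC trend subtracted, dox in rtTA cells gave 20 and rtTA without dox 3. Base percentages and length gave 6 (dox in rtTA cells), 3 (rtTA without dox) and 20 (rtTA with dox); with end bases added, 6, 2 and 18; end bases and length alone gave 24 for dox in rtTA cells.

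The 67 microRNAs whose dox ratios differ with rtTA became 36 with the G trend subtracted, and the correlation of -0.19 became -0.064 (G) and -0.016 (GC). The lowest correlation between libraries, 0.980, was 0.988 without a floor. Lists standing apart (1, 2, 5 and 2 in the order above) became 1 for dox without rtTA at a floor of 5 counts, 1 for dox without rtTA and 1 for rtTA with dox at 100 counts, and 4 and 1 for these without passenger strands. With the G trend subtracted they became 0 (dox in rtTA cells), 1 (dox without rtTA) and 1 (rtTA with dox), with the GC trend 0 (dox in rtTA cells), and without near-identical microRNAs 0 (dox without rtTA) and 2 (rtTA without dox); equal counts need not be the same lists, since for dox in rtTA cells miR-34 then stood apart in place of let-7, and for rtTA with dox in place of muscle. The miR-30 median of 0.22 for rtTA without dox was -0.0048 without passenger strands, and the let-7 median of -0.40 for dox in rtTA cells was 0.048 with the GC trend subtracted. The rtTA term of the additive edgeR fit called 1 without a floor (0 with it), and the fit of the induced library against 3 called 4 with G content offsets (48 without).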

Other observations

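All tests in this part were chosen after the results had been seen. The induced library lay outside the range of the other libraries for 70.2% of the 372 microRNAs, against 41.1%, 55.4% and 33.3% for the others, where 50% is the share chance gives. A fit of 1 library against the other 3, which treats those 3 as replicates although their conditions differ, assumes that the lone library varies like them and called 5 of 172 unchanged microRNAs in simulated data, called 48 microRNAs for the induced library with edgeR (18 higher, 30 lower; 61 with DESeq2) and 0 for each of the other libraries, where edgeR gave 2, 14 and 1 at an unadjusted p below 0.05 and DESeq2 called 0 with 4, 12 and 0. With G content offsets per library it called 4 for the induced library. In the fits of the other libraries the induced library sits among the 3 that supply the spread, which can hide differences there. The calls for the induced library describe 1 library and do not test induction.

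In 10-fold cross-validation across microRNAs, the percentage of G explained 50.8% of the variance of the dox ratios in rtTA cells and 47.2% of the rtTA ratios with dox, but 1.43% and -1.86% in the comparisons without the induced library. GC content explained 19.4%, 13.9%, 3.03% and 22.9% (dox with rtTA, dox without rtTA, rtTA without dox, rtTA with dox), so dox without rtTA also moved with composition, in the opposite direction (correlation with GC -0.39 against 0.46).

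The arms of 1 hairpin come from 1 transcript, but arms were paired by name. Of the 508 microRNAs, 62 match more than 1 precursor, so some pairs, such as let-7f and let-7f*, do not share a single source. Across 100 pairs with both arms past the floor, the ratios of the arms had a correlation of 0.33 (0.17 to 0.47) for dox without rtTA and 0.36 (0.19 to 0.53) for rtTA without dox. The intervals come from resampling pairs, which are not independent replicates. For dox with rtTA it was -0.15 (-0.37 to 0.085) and for rtTA with dox 0.05 (-0.14 to 0.24). After subtraction of the G trend these became 0.25, 0.36, -0.04 and 0.06.

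miR-16, encoded beside miR-15b within Smc4 on chromosome 3 and again on chromosome 14, had a ratio of -0.30 with dox in rtTA cells, against -1.56 for miR-15b.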
